A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

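RNA from yeast cells held for 6 h in sporulation medium, 2 samples from young cells and 2 from old cells, was compared on 4 two-colour Agilent arrays with RNA from vegetative cells of the same strain. Per the labels, 200 ng of RNA was used, sporulating RNA carried Cy3 and vegetative RNA Cy5. The intensity values, mean spot and median local background brightness per channel, were read by the authors with Agilent Feature Extraction 9.1.3.1, per the file headers. The files also hold processed intensities, which per the file headers were background subtracted, spatially detrended and dye-normalised linearly on rank-consistent probes by that software. The log10 values are, per the file headers, logs of the ratio of processed Cy5 over Cy3. The deposited log2 table gives vegetative over sporulating signal. It runs parallel to the scanner's ratio on each array (slope about 1) but is shifted by a constant per array whose origin is not stated, and 102 to 189 probes per array are blank.

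The mean and background signals were used here, with limma 3.58.1 in R 4.3.3. Signals were background corrected by normexp with an offset of 50. Log2 ratios were turned to sporulating over vegetative and loess-normalised within each array, with control and outlier spots given no weight. Spots that the software marked as non-uniform or as population outliers were left out, and the 2 spots of each gene were averaged. A gene was tested if it was well above background in at least 1 channel on at least 2 of the 4 arrays. All gene spots and all 77 negative controls carried that mark, so the filter removed no gene. Of the 6256 genes, 5756 were matched to a symbol or locus tag and 500 kept the name in the file. No genome build comes with the files, so no coordinates are given. In 8 genes young replicate 2 had no value.

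One limma fit with a young and an old coefficient gave 3 comparisons: young against vegetative, old against vegetative, and old minus young. Moderated statistics came from eBayes with its defaults, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold size was no part of the call. The median SE was 0.103 for each age against vegetative cells and 0.145 for old minus young, on the log2 scale. The vegetative sample entered as the second channel of each array, so the reference and a constant dye effect cancel only in old minus young. For the reference this assumes the same vegetative signal on every array. Over genes, the Cy5 signals of young replicate 2 had correlations of 0.943 to 0.944 with the other arrays, which had 0.992 to 0.998 among themselves. No dye swap was made. Young arrays lay in one row of the slide and old arrays in another, so array position and age are confounded. Replicate numbers did not pair the arrays: the deviations of replicate 1 from replicate 2 had a correlation of -0.0965 across genes between young and old, and genes are not independent replicates.

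Lists of genes, 35 in all, were fixed before the data were examined, as were the comparisons, tests, filters and the alternatives from the first plan. Camera with a preset correlation of 0.01 tested each list with at least 5 measured members against all other genes, with Benjamini-Hochberg adjustment over the lists, and camera with an estimated correlation was run beside it. With the preset correlation 24 lists were called in young cells, 23 in old cells and 23 in old against young cells. With an estimated correlation camera called 0 in each, with adjusted p of at least 0.319, 0.354 and 0.299. That form has few residual degrees of freedom, since they come from the arrays, while the preset form takes them from the genes. The contrast therefore cannot show that correlation removed the calls. Between the ages the haploid and mating type list had an estimated correlation of -0.029, below the preset 0.01. Its camera adjusted p still went from 9.05e-06 to 0.299. Other lists lay far above the preset, with 0.949 for ribosome biogenesis, 0.583 for polymerase I and III and 0.571 for cytosolic ribosomal protein genes. For such lists the preset p-values are likely too small. Preset p-values do not measure spread between arrays. For each list, genes past the test over all genes were counted, and again with p adjusted over the list alone.

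Named genes were chosen by a fixed rule. IME1, IME2 and NDT80 were always named, then the 8 largest rises and 8 largest falls past the threshold with both replicates on the same side. For each described list the rule took the 2 largest changes past the threshold in the direction of the median and the largest in the other direction, or, where none passed, the 2 genes with the smallest p. For a gene saturated in one channel on both arrays of a group the measured ratio was given as a bound, and for a gene saturated in both channels no fold was given.

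The alternatives tried were no background subtraction, an offset of 10, median centring in place of loess, the processed signals, the deposited table, scale normalization between arrays, eBayes with trend and robust options, replicate number as a block, the young arrays averaged as 1 replicate, the Cy3 channel alone, and leaving out each array. A filter against the negative controls and averaging of the old arrays as 1 replicate were added after seeing the data. The procedure was tested on simulated data with 200 changed genes among 6248. Noise was independent between genes, with the same spread for a gene on young and old arrays, unlike in the data. At a log2 change of 1 it recovered 96% of them in young cells, 95% in old cells and 81% in old against young cells. At a change of 2 it recovered 99.5%, 99% and 99%, and at 0.5 it recovered 0% in each by limma. Against vegetative cells far more genes were called in the data, 72.7% in young and 80.1% in old cells. The adjusted threshold is then easier to pass, so the 0% is not the power there. SKI8 passed at -0.39 in young cells and RAD9 at -0.35 in old cells. In 20 simulations with no effect and unequal spread between the groups, limma called a mean of 0 genes in old against young cells. Noise was again independent between genes. In the data genes shifted together between the young arrays: 97 of 98 ribosome biogenesis genes were higher on young replicate 1, by a median of 1.26. The simulations therefore cannot show how many calls between the ages are false. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.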

Results

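Gene expression was measured in budding yeast (Saccharomyces cerevisiae) on 4 two-colour arrays, to ask how replicative age affects the response to conditions that induce meiosis and spore formation. Cells of about 4 generations (young) and of about 15 generations (old) were held for 6 h in sporulation medium (0.2% KAC in the labels). RNA from 2 young and 2 old samples was labelled with Cy3. RNA from vegetative cells of the same strain, grown in the rich medium YPD, was labelled with Cy5 and hybridised to every array. Each array measured 6256 genes with 1 probe each, spotted in duplicate. The median gene spot was 15.4 to 22.0 times as bright as the median negative control in the Cy3 channel, and 8.97 to 25.8 times in the Cy5 channel, where young replicate 2 was dimmest. That array also had the largest SD between a gene's duplicate spots, at 0.277 log2 units against 0.0905 to 0.125 on the other arrays. The old arrays lay closer together than the young arrays: the SD over genes of the difference between replicates was 0.139 log2 units in old and 0.480 in young cells. Over genes, which are not independent replicates, the log2 ratios of young replicate 2 had correlations of 0.950 and 0.949 with the old arrays and of 0.942 with young replicate 1, so by this measure it lay no nearer to its own group. By the SD over genes of the difference, young replicate 2 lay nearer to young replicate 1 (0.480) than to the old arrays (0.537 and 0.562). The number of arrays, 2 per group, limits the precision of every value. In the array titles the young arrays share a number, with a letter added on young replicate 2, and the old arrays carry different numbers, whose meaning is not stated. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values are log2 of sporulating over vegetative signal, as the mean of 2 arrays ± SE from the fit. The fit pools 1 spread per gene over all 4 arrays. The ± is thus not the spread of a group's own 2 arrays, and young values borrow the closeness of the old arrays. The ribosome biogenesis gene BRX1 lay at -1.54 and -3.50 on the young arrays, with an SE of 0.47. The polymerase subunit gene RPA12 had an SE of 0.33 in old cells and an SD of 0.040 between the old arrays.

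The first comparison asked how young cells in sporulation medium differ from vegetative cells. Genes of acetate use, starvation and meiosis rose, and genes of ribosome production fell. Among the largest rises were PDH1 (6.45 ± 0.093) and CIT3 (5.93 ± 0.23), which encode mitochondrial enzymes of the methylcitrate cycle, and the small heat shock gene HSP12 (6.36 ± 0.11). The malate synthase gene MLS1, saturated in the sporulating channel on 1 young array, rose by 6.06, which is a lower limit. The allantoin and amino acid permease genes DAL4 (5.81 ± 0.15) and GAP1 (5.71 ± 0.27) and PHO92 (5.69 ± 0.088) rose too. ACS1, which encodes the acetyl-CoA synthetase of cells without glucose, was saturated in the sporulating channel and was at least 51.4-fold higher. The hexose transporter gene HXT3 fell by 4.81 ± 0.13. YOL014W was near the negative controls (at most their mean plus 3 SD) in the sporulating channel on young replicate 2 and lay at a log2 ratio of -5.48 or lower. The amino acid permease gene BAP3 (-4.64 ± 0.090), the glucose repressor gene MIG2 (-4.47 ± 0.13) and the ribosomal protein genes RPS22B (-4.76 ± 0.22), RPL23B (-4.64 ± 0.17), RPL23A (-4.39 ± 0.11) and RPL41B (-4.34 ± 0.13) fell as well. Every gene named for this comparison had the same sign on both young arrays and an adjusted p of at most 0.0122 by limma. The naming rule required the shared sign of the largest rises and falls, so for them it is no test.

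The meiotic programme was already induced in young cells, and the haploid and mating type list was shifted up beside it. IME1 and IME2, the regulator and the kinase that start meiosis, rose by 3.62 ± 0.13 and 3.52 ± 0.096. NDT80, the transcription factor of the middle phase, rose by 3.43 ± 0.12. Of the early meiotic genes of recombination and the synaptonemal complex, 32 of 34 rose (32 adjusted over the list alone), led by MEI5 (4.86 ± 0.14) and MEK1 (4.81 ± 0.12). SKI8, which also acts in RNA decay, fell by 0.39 ± 0.078, a call lost when either old array was left out of the shared fit. Of the middle sporulation genes, 34 of 43 rose (35 adjusted over the list alone), among them SPS2 (5.29 ± 0.17) and SPS4 (4.73 ± 0.19), and the S-phase cyclin gene CLB6 fell by 1.15 ± 0.092. Of the late sporulation and spore wall genes, 17 of 18 rose (17 adjusted over the list alone), with the chitin deacetylase genes CDA1 (3.74 ± 0.081) and CDA2 (3.54 ± 0.24) in front. Of the meiotic entry regulators, 15 of 22 rose (15 adjusted over the list alone) and 2 fell, including the repressor gene YHP1 (-1.39 ± 0.081). Of the haploid and mating type genes, 18 of 29 rose (18 adjusted over the list alone), with AXL1 (1.97 ± 0.078) and RDH54 (1.51 ± 0.098) in front, while AGA1 fell by 0.50 ± 0.080 (-0.16 and not past the test with median centring). The 5 list medians were 2.50 for the early, 1.68 for the middle, 2.07 for the late, 0.91 for the entry and 0.56 for the mating type list, the last 0.92 with processed signals. Camera placed each above all other genes (adjusted p between 3.01e-09 and 0.00605; adjusted p between 0.319 and 0.392 with an estimated correlation).

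Genes of non-fermentative carbon use, nutrient scavenging and stress rose with them. All 29 measured genes of gluconeogenesis, the glyoxylate cycle and acetate use rose (29 adjusted over the list alone), with a median of 3.73. Of the stress response genes, 39 of 47 rose (40 adjusted over the list alone), with PGM2 (4.52 ± 0.23) beside HSP12, and the peroxidase gene GPX2 fell by 3.52 ± 0.095. Of the nitrogen starvation genes, 26 of 31 rose (26 adjusted over the list alone), while the asparaginase gene ASP3-1 fell, a call lost without either old array. Its sporulating signal was near the negative controls on young replicate 2, so no size is given. Of the autophagy and vacuolar protease genes, 22 of 29 rose (22 adjusted over the list alone), led by ATG8 (4.96 ± 0.087) and APE1 (3.70 ± 0.10), while ATG10 fell by 1.41 ± 0.094. Of the GCN4 targets of amino acid biosynthesis, 45 of 51 rose (45 adjusted over the list alone), with ARG3 (4.86 ± 0.11) high among them, and LYS9 fell by 1.63 ± 0.083. Of the methionine and sulfate genes, 16 of 23 rose (17 adjusted over the list alone), including MET28 (4.69 ± 0.11) and the sulfate permease gene SUL1 (4.91 ± 0.089), while the methionine permease gene MUP1 fell by 1.75 ± 0.086. The medians of the last 5 lists were 2.04, 2.55, 1.67, 1.89 and 1.81. The GCN4 median was 1.10 with median centring, 0.93 with processed signals and 0.76 with the deposited value table. Camera called these 6 lists (adjusted p between 3.01e-09 and 0.0018; adjusted p = 0.319 with an estimated correlation).

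Further lists were shifted up in young cells. Of the retrograde response genes, 11 of 13 rose (11 adjusted over the list alone), CIT3 and PDH1 among them. Of the DNA damage genes, 15 of 24 rose (14 adjusted over the list alone), with the glycosylase gene MAG1 (2.20 ± 0.084) in front. Of the subtelomeric COS and YRF1 genes, 16 of 20 rose (17 adjusted over the list alone), such as COS6 (2.57 ± 0.093), and COS12 fell by 1.69 ± 0.14. Of the seripauperin and anaerobic wall genes, 26 of 30 rose (26 adjusted over the list alone), with TIR2 (1.90 ± 0.088) and PAU22 (1.68 ± 0.14) in front, and TIR1 fell by 1.68 ± 0.16. Their medians were 2.92, 0.57, 1.83 and 1.41 (adjusted p between 3.41e-05 and 0.0065; adjusted p between 0.319 and 0.475 with an estimated correlation). With the deposited value table the first 3 were 1.38, 0.37 and 0.84, their lowest values over 15 alternatives, all of which called the lists. Of the TCA cycle and respiratory chain genes, 31 of 48 rose (31 adjusted over the list alone), with CIT1 (4.13 ± 0.092) and NDE2 (3.95 ± 0.15) in front, and CYC1 fell by 1.64 ± 0.19. Of the proteasome genes, 24 of 34 rose (24 adjusted over the list alone), with their regulator RPN4 (1.47 ± 0.16) and RPT1 (1.41 ± 0.083) in front, and PUP3 fell by 1.05 ± 0.14. These 2 medians were 1.09 and 0.61 after loess but -0.22 and -0.071 with the scanner's processed signals. Camera called both lists after loess (adjusted p between 0.00027 and 0.00113; adjusted p between 0.392 and 0.476 with an estimated correlation) and neither with processed signals (adjusted p = 0.683 and 0.474). Of 15 alternatives 12 called each list, with an adjusted p of up to 0.702 and 0.816, and the calls were also lost with median centring and with the deposited values.

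Growth and division genes fell in young cells. Of the cytosolic ribosomal protein genes, 124 of 137 fell (125 adjusted over the list alone), with a median of -2.06 (-3.60 with the deposited value table), while RPL15B (1.17 ± 0.084) rose. Probes for near-identical paralogues such as RPL23A and RPL23B may not tell the copies apart. Of the mitochondrial ribosomal protein list, 69 of 71 fell (69 adjusted over the list alone), with a median of -1.95 and with MRPL49 (-3.05 ± 0.13) and MRPL20 (-3.03 ± 0.083) lowest. MRP8, which is not an established ribosomal subunit, rose by 1.58 ± 0.10. Of the ribosome biogenesis genes, 82 of 98 fell (83 adjusted over the list alone), such as GAR1 (-2.57 ± 0.26) and BRX1 (-2.52 ± 0.47), the latter at -1.54 without young replicate 2. The list's median was -0.72 on young replicate 1 and -2.08 on young replicate 2, and -1.38 with both. Of the RNA polymerase I and III subunit genes, 22 of 26 fell (23 adjusted over the list alone), with RPA12 (-3.20 ± 0.33) and RPC17 (-3.13 ± 0.27) lowest and a median of -1.30. Camera called these 4 lists (adjusted p between 1.42e-19 and 4.09e-05; adjusted p between 0.319 and 0.568 with an estimated correlation).

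Of the mitotic G2/M genes, 13 of 15 fell (13 adjusted over the list alone), with the mitotic cyclin gene CLB2 (-2.38 ± 0.16) and HOF1 (-1.99 ± 0.080) lowest, and the kinase gene DBF2 (0.89 ± 0.088) rose. Of the G1/S genes, 12 of 18 fell (12 adjusted over the list alone), with the cyclin genes CLN2 (-2.06 ± 0.14) and PCL1 (-1.98 ± 0.14) lowest, and the transcription factor gene SWI4 (0.83 ± 0.13) rose. The medians were -0.68 and -0.85 (adjusted p between 0.000739 and 0.00487; adjusted p = 0.319 with an estimated correlation), and the G1/S list was not called with median centring (adjusted p = 0.0538, the highest over 15 alternatives). The mitochondrially encoded genes were not shifted as a list (median 0.17, -0.29 with median centring and 1.02 with the negative-control filter; adjusted p = 0.406). Of these, 6 of 14 rose (6 adjusted over the list alone), including ATP8 (1.63 ± 0.15) and COX3 (1.58 ± 0.18), and 3 fell, including the intron-encoded AI1 (-1.01 ± 0.12). In all, 4551 of 6256 genes changed in young cells by limma (2339 rose and 2212 fell, 2380 of them at least 2-fold). Loess centres each array on its typical gene (median log2 ratio 0.022 in young cells), although 72.7% of genes were called changed. Rises and falls are thus relative to that gene, not per cell, and their near-even split follows largely from the centring. Sporulating RNA always carried Cy3 and vegetative RNA Cy5, so a gene's dye effect is part of its ratio. The vegetative RNA counts as 1 control sample whose own spread is not in the test.

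The second comparison asked the same of old cells. Genes of spore formation now stood among the largest rises: SPS2 (7.39 ± 0.17), the sporulation septin gene SPR28 (6.68 ± 0.20), SPO20, which encodes a SNARE of the prospore membrane (6.40 ± 0.14), and the meiotic pairing gene HOP2 (6.53 ± 0.16). They stood beside PHO92 (6.74 ± 0.088), PDH1 (6.40 ± 0.093) and CIT3 (6.26 ± 0.23). MLS1, SPS4 and ACS1 were saturated in the sporulating channel and were at least 76.3, 56.7 and 47.9-fold higher. IME1 rose by 3.82 ± 0.13, IME2 by 4.37 ± 0.096 and NDT80 by 5.44 ± 0.12. Among the largest falls were MIG2 (-5.76 ± 0.13), RPS22B (-5.48 ± 0.22), BAP3 (-5.19 ± 0.090), HXT3 (-5.19 ± 0.13), RPL23B (-5.14 ± 0.17), YOL014W (-5.10 ± 0.10) and RPL23A (-4.92 ± 0.11). The aldehyde dehydrogenase gene ALD6 was saturated in the vegetative channel and lay at a log2 ratio of -5.32 or lower. Every gene named for this comparison had the same sign on both old arrays and an adjusted p of at most 0.0155 by limma. As in young cells, the naming rule required the shared sign of the largest rises and falls.

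The early, middle and late meiotic lists were shifted up in old cells. So were the meiotic entry regulators, which include the repressor genes RME1 and YHP1, and the haploid and mating type genes. Of the early meiotic genes, 33 of 34 rose (33 adjusted over the list alone), with MEI5 (5.72 ± 0.14) beside HOP2, while SKI8 fell by 0.41 ± 0.078, a call lost without either old array. Of the middle sporulation genes, 41 of 43 rose (41 adjusted over the list alone), and limma called 0 falls (0 at an unadjusted p under 0.05). Of the late sporulation and spore wall genes, 17 of 18 rose (17 adjusted over the list alone), with CDA1 (6.00 ± 0.081) and CDA2 (5.69 ± 0.24) in front. Of the meiotic entry regulators, 17 of 22 rose (17 adjusted over the list alone), and YHP1 fell by 2.03 ± 0.081. Of the haploid and mating type genes, 23 of 29 rose (23 adjusted over the list alone), with AXL1 (2.63 ± 0.078) and RME1 (2.09 ± 0.10), a repressor gene of IME1, in front, and AGA1 fell by 0.69 ± 0.080. Their medians were 3.59, 3.44, 3.47, 1.42 and 1.03 (adjusted p between 1.33e-11 and 0.00277; adjusted p = 0.354 with an estimated correlation). Of the iron regulon genes, which serve iron uptake, 18 of 25 rose (18 adjusted over the list alone), with the haem oxygenase gene HMX1 (2.98 ± 0.098) and the cell wall mannoprotein gene FIT1 (2.86 ± 0.10) in front, and the reductase gene FRE4 fell by 3.19 ± 0.083. That list's median was 0.93 (adjusted p = 0.00695; adjusted p = 0.423 with an estimated correlation).

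Lists of gluconeogenesis, stress, nitrogen starvation, autophagy and GCN4 targets were shifted up in old cells as well. All 29 gluconeogenic genes rose (29 adjusted over the list alone), with a median of 4.38. Of the stress response genes, 39 of 47 rose (39 adjusted over the list alone), with HSP12 (6.09 ± 0.11) and PGM2 (4.93 ± 0.23) in front, and GPX2 fell by 3.47 ± 0.095. Of the nitrogen starvation genes, 25 of 31 rose (25 adjusted over the list alone), with GAP1 (6.16 ± 0.27) and DAL4 (5.58 ± 0.15) in front, and the regulator gene URE2 fell by 0.82 ± 0.089. Of the autophagy and vacuolar protease genes, 25 of 29 rose (25 adjusted over the list alone), with ATG8 (5.43 ± 0.087) and APE1 (3.82 ± 0.10) in front, and ATG10 fell by 1.47 ± 0.094. Of the GCN4 targets, 40 of 51 rose (41 adjusted over the list alone), with the arginine gene ARG4 (4.95 ± 0.16) high among them, and LYS9 fell by 1.79 ± 0.083. The last 4 medians were 2.31, 2.42, 2.17 and 1.21, the GCN4 median falling to 0.54 with the deposited value table. Camera called these 5 lists (adjusted p between 2.38e-08 and 0.000144; adjusted p = 0.354 with an estimated correlation), the GCN4 list not with processed signals (adjusted p = 0.058, the highest over 15 alternatives).

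Further lists were shifted up in old cells. Of the retrograde response genes, 12 of 13 rose (12 adjusted over the list alone), and of the DNA damage genes, 16 of 24 rose (16 adjusted over the list alone). The latter included the nuclease gene DIN7 (2.57 ± 0.12) and MAG1 (2.74 ± 0.084), while RAD9 fell by 0.35 ± 0.079, a call lost without either old array and with median centring. Of the seripauperin genes, 26 of 30 rose (26 adjusted over the list alone), such as PAU3 (1.86 ± 0.13) and PAU14 (1.82 ± 0.14), and TIR1 fell by 1.65 ± 0.16. Of the COS and YRF1 genes, 16 of 20 rose (16 adjusted over the list alone), such as COS6 (2.99 ± 0.093) and COS5 (2.42 ± 0.085), and COS12 fell by 1.09 ± 0.14. The medians were 2.64, 0.85, 1.52 and 1.76 (adjusted p between 0.000101 and 0.00219; adjusted p between 0.354 and 0.449 with an estimated correlation). With the deposited value table the retrograde, DNA damage and COS medians were 1.63, 0.55 and 0.78, their lowest values over 15 alternatives, all of which called the lists. Of the respiratory genes, 31 of 48 rose (31 adjusted over the list alone), such as NDE2 (4.42 ± 0.15) and CIT1, which was saturated in the sporulating channel on 1 old array and had 4.06 as a lower limit, and CYC1 fell by 2.06 ± 0.19. Of the proteasome genes, 29 of 34 rose (29 adjusted over the list alone), such as RPN4 (1.82 ± 0.16) and RPN5 (1.81 ± 0.11), and PUP3 fell by 0.74 ± 0.14, a call lost without either old array. These 2 medians were 0.84 and 1.04 after loess (adjusted p between 2.92e-05 and 0.00219; adjusted p between 0.405 and 0.423 with an estimated correlation) but -0.32 and -0.027 with processed signals. Each list was called in 12 of 15 alternatives, with an adjusted p of up to 0.865 and 0.879, and not with median centring, processed signals or deposited values.

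Growth genes fell in old cells. Of the cytosolic ribosomal protein genes, 135 of 137 fell (135 adjusted over the list alone), and RPL15B (1.43 ± 0.084) rose. Of the mitochondrial ribosomal protein list, 70 of 71 fell (70 adjusted over the list alone), with MRPL49 (-3.38 ± 0.13) and MNP1 (-3.30 ± 0.11) lowest, and MRP8 (2.99 ± 0.10) rose. Of the ribosome biogenesis genes, 97 of 98 fell (97 adjusted over the list alone), with the small nucleolar ribonucleoprotein genes NOP1 (-4.32 ± 0.42) and NOP58 (-4.21 ± 0.21) lowest. Of the polymerase I and III genes, 24 of 26 fell (24 adjusted over the list alone), with RPA12 (-4.42 ± 0.33) and RPC17 (-4.01 ± 0.27) lowest. Of the G1/S genes, 11 of 18 fell (11 adjusted over the list alone), with CSI2 (-2.82 ± 0.26) and PCL1 (-2.79 ± 0.14) lowest, and SWI4 (1.67 ± 0.13) rose. The medians were -2.42, -2.24, -3.02, -2.17 and -0.99, the first -3.79 with the deposited value table (adjusted p between 3.24e-21 and 0.0167; adjusted p between 0.354 and 0.513 with an estimated correlation). The G1/S list was called in 12 of 15 alternatives, and not with median centring, processed signals or deposited values (adjusted p of up to 0.0797). The mitochondrially encoded genes were not shifted as a list (median 0.024, -0.076 with median centring and 0.59 with the deposited value table; adjusted p = 0.93), with COX3 (0.72 ± 0.18), a call lost without either old array, and AI1 (-1.91 ± 0.12) among those past the test. OLI1 was saturated in both channels, so no fold is given. In all, 5009 of 6256 genes changed in old cells by limma (2570 rose and 2439 fell, 2965 at least 2-fold). These counts are again relative to the typical gene of each array.

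Across both comparisons, 2181 genes rose and 2055 fell at both ages, where independent lists of the same lengths would share 961 and 862. Simulated groups with no effect and a shared control gave a mean of 18.6 genes called the same way in both and at most 38 in 20 simulations. The simulated control deviated only by the spread between replicate arrays. The real control's own deviation and the dye effect shared by both ages were not measured and may be larger. The simulation therefore cannot size their part in the overlap. The vegetative control could not be split, so part of the excess may come from the control that both comparisons share.

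**Figure D1:**
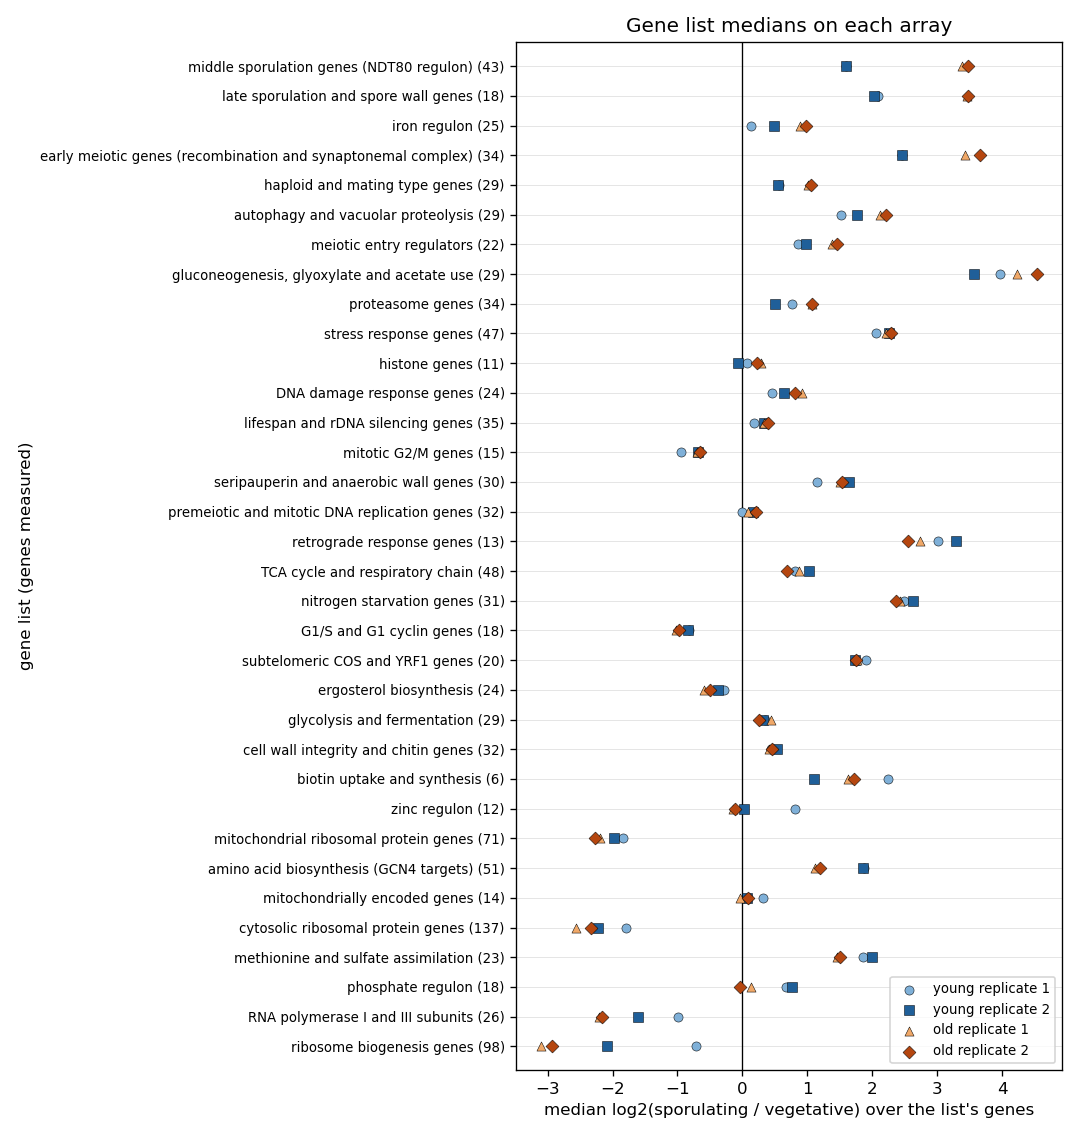
Median log2 ratio of sporulating over vegetative signal (horizontal axis) over the measured genes of each gene list shown (vertical axis, with the number of genes), 1 symbol per array, in order of the difference between old and young cells. The middle sporulation genes lie at 1.59 and 1.60 on the young arrays and 3.38 and 3.48 on the old arrays, and the ribosome biogenesis genes at -0.72 and -2.08 against -3.10 and -2.93.

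The third comparison set old against young cells directly, to ask whether the response differs with age. Genes of the meiotic divisions and of spore formation were higher in old cells: of the middle sporulation genes, 40 of 43 rose (41 adjusted over the list alone), and the median difference was 1.82 (1.12 under scale normalization between arrays). The largest rises were PFS1 (3.21 ± 0.26), YFL012W (3.14 ± 0.25), SPR28 (2.95 ± 0.28), SPO20 (2.93 ± 0.20), RRT12 (2.93 ± 0.30), YGR273C (2.84 ± 0.35), SPS18 (2.82 ± 0.12) and YOR365C (2.77 ± 0.22), with adjusted p between 0.0125 and 0.0252. The vegetative signal of PFS1, YFL012W and YGR273C was near the negative controls on young replicate 2, so their ratios there are uncertain. They were 2.89, 3.47 and 3.31 higher without young replicate 2. Of these genes, PFS1, SPR28, SPO20 and SPS18 belong to the middle list. NDT80 itself was 2.02 ± 0.17 higher (adjusted p = 0.0138). IME2 was 0.85 ± 0.14 higher (adjusted p = 0.0412) but lay at -0.13 under scale normalization. IME1 did not pass the test (0.20 ± 0.19, adjusted p = 0.484; -0.74 under scale normalization, and 0.40 and past the test without young replicate 1). The largest falls were those of the phosphate transporter gene PHO84 (-4.04 ± 0.40), YDL038C (-2.68 ± 0.13), the nucleolar genes NOP58 (-2.48 ± 0.30), NOC2 (-2.42 ± 0.11), NOP56 (-2.37 ± 0.39) and RRP3 (-2.25 ± 0.34), the phosphate-responsive gene SPL2 (-2.47 ± 0.12) and the amino acid permease gene AGP1 (-2.37 ± 0.42), with adjusted p between 0.0125 and 0.049.

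Of the late sporulation and spore wall genes, 12 of 18 rose (14 adjusted over the list alone) in old against young cells, among them the glucanase gene SPR1 (2.63 ± 0.17) and CDA1 (2.26 ± 0.11). Of the early meiotic genes, 13 of 34 rose (27 adjusted over the list alone), led by HOP2 (2.30 ± 0.22) and MEI4 (1.67 ± 0.26). HOP2 was near the negative controls in the vegetative channel on young replicate 2, so its ratio there is uncertain, and it was 2.05 higher without that array. The late median was 1.53, 0.87 under scale normalization between arrays and 2.15 in the Cy3 channel alone. The early median was 0.85, and 0.19 under scale normalization. Of the haploid and mating type genes, 5 of 29 rose (14 adjusted over the list alone), with STE18 and STE4, the gamma and beta subunit genes of the pheromone receptor's G protein, at 1.43 ± 0.11 and 1.11 ± 0.14. Their median was 0.46, 0.22 under scale normalization and 0.20 in the Cy3 channel alone. Camera called these 4 lists (adjusted p between 6.07e-28 and 9.05e-06; adjusted p = 0.299 with an estimated correlation), as did all 16 alternatives. Of the meiotic entry regulators, 1 of 22 rose (6 adjusted over the list alone). Their median was 0.39 (adjusted p = 0.0212; adjusted p = 0.502 with an estimated correlation), but -0.032 and not called under scale normalization (adjusted p = 0.917, the highest over 16 alternatives). The call was lost as well with median centring, processed signals and deposited values, and 12 of the 16 alternatives kept it.

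Iron uptake genes were higher in old cells. Of the iron regulon, 13 of 25 rose (17 adjusted over the list alone), with a median of 0.87 (adjusted p = 1.61e-07; adjusted p = 0.299 with an estimated correlation). Adjusted over the list alone, 2 iron genes fell. The ferroxidase gene FET3 was 1.99 ± 0.13 higher and the siderophore transporter gene ARN2 1.93 ± 0.18 higher (adjusted p = 0.0125 and 0.0158). Autophagy and vacuolar protease genes shifted up by a median of 0.44, with ATG3 (0.92 ± 0.15) rising and the carboxypeptidase gene CPS1 (-0.87 ± 0.11) falling. That median was 0.088, and not called, under scale normalization between arrays (adjusted p = 0.656, the highest over 16 alternatives, of which 15 called the list). Proteasome genes shifted up by 0.30 (0.17 without young replicate 2), and 14 of 16 alternatives called them. The call was lost with median centring (median 0.088, adjusted p = 0.127, the highest of these) and under scale normalization (median 0.14, adjusted p = 0.0903). The adjusted p of these 2 lists was 2.26e-05 and 4.05e-05 (adjusted p = 0.299 and 0.535 with an estimated correlation). In the autophagy list 1 gene rose and 1 fell (3 and 1 adjusted over the list alone). Limma called 0 proteasome genes, also when adjusted over the list alone (11 rose at an unadjusted p under 0.05), and PRE4 (0.56 ± 0.12) and RPN2 (0.50 ± 0.12) had the smallest p.

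Further upward shifts were called for lists whose direction or call also depended on the normalization or on single arrays. Stress response genes had a median of 0.27 (-0.27 under scale normalization, 0.038 in the Cy3 channel alone and 0.17 without young replicate 1), and 1 of 47 rose (0 adjusted over the list alone), with 10 higher at an unadjusted p under 0.05 by limma; it was the trehalose synthesis gene TSL1 (1.01 ± 0.17). DNA damage genes had a median of 0.20 (-0.050 under scale normalization), and 1 of 24 rose (2 adjusted over the list alone), led by DIN7 (1.67 ± 0.18). Histone genes had a median of 0.25 (0.48 with the deposited value table), not called without young replicate 2 (0.17) or old replicate 1 (0.19), and 1 of 11 rose (2 adjusted over the list alone), led by the H2A.Z gene HTZ1 (0.76 ± 0.13). The gluconeogenic median was 0.35 (-0.60 under scale normalization between arrays, where the list was called down with adjusted p = 0.00137, against at most 0.509 over 16 alternatives), and not called without young replicate 2 (0.067) or old replicate 2 (0.22); it was 0.59 without young replicate 1 and 0.56 without old replicate 1. The seripauperin median was 0.16 (-0.18 under scale normalization), 0.35 without young replicate 2, and not called without young replicate 1 (-0.043), old replicate 1 (0.17) or old replicate 2 (0.14). In each of the last 2 lists limma called 0 genes, also when adjusted over the list alone, and 6 and 5 were higher at an unadjusted p under 0.05. FBP1 (0.76 ± 0.14), SFC1 (0.69 ± 0.15; -0.30 under scale normalization), DAN4 (0.44 ± 0.11) and TIR2 (-0.46 ± 0.13) had their smallest p. Camera called the 5 lists with adjusted p between 0.0058 and 0.0463; adjusted p between 0.299 and 0.647 with an estimated correlation. Of the 16 alternatives 14 called the stress, 14 the DNA damage, 11 the histone, 11 the gluconeogenic and 7 the seripauperin list as up.

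Ribosome production genes were lower in old than in young cells. Of the ribosome biogenesis genes, 8 of 98 fell (68 adjusted over the list alone). The median was -1.47, -0.98 under scale normalization between arrays, -0.81 without young replicate 1 and -2.12 without young replicate 2. Of the RNA polymerase I and III subunit genes, 2 of 26 fell (4 adjusted over the list alone): RPA190, the gene of the largest polymerase I subunit, fell by 1.30 ± 0.13, and RPC10 fell by 1.41 ± 0.23 but lay at 0.31 in the Cy3 channel alone. That list's median was -0.84, -0.42 under scale normalization, -0.38 without young replicate 1 and -1.27 without young replicate 2. Of the cytosolic ribosomal protein genes, 12 of 137 fell (36 adjusted over the list alone), among them RPS2 and RPL4A by the fit. Both were saturated in the vegetative channel on all 4 arrays, so no size is given. The list's median of -0.57 was -0.37 without young replicate 1, -0.27 with the deposited value table and 0.032, and not called, under scale normalization. Camera called the 3 lists (adjusted p between 2.3e-19 and 2.26e-05). With an estimated correlation camera gave an adjusted p between 0.535 and 0.548. The estimated correlations were 0.949, 0.583 and 0.571 against the preset 0.01, so the preset p-values of these lists are likely too small.

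Biosynthetic and phosphate genes were lower in old cells as well. Of the GCN4 targets, 9 of 51 fell (31 adjusted over the list alone), with the branched-chain aminotransferase gene BAT1 (-2.06 ± 0.14) and the arginine gene ARG8 (-2.02 ± 0.16) lowest. Of the methionine and sulfate genes, 7 of 23 fell (10 adjusted over the list alone), with the cystathionine lyase gene CYS3 (-1.90 ± 0.19) and MET14 (-1.34 ± 0.11) lowest. Of the phosphate regulon, 5 of 18 fell (11 adjusted over the list alone), PHO84 and SPL2 most, and 3 rose when adjusted over the list alone. The medians were -0.49, -0.59 and -0.66 (adjusted p between 4.27e-10 and 0.000742; adjusted p = 0.299 with an estimated correlation), and the first 2 were -0.98 and -0.99 under scale normalization between arrays. Of the mitochondrially encoded genes, 2 of 14 fell (8 adjusted over the list alone), the cytochrome b gene COB (-0.89 ± 0.15) and the endonuclease gene SCEI (-0.77 ± 0.13). Of the cell wall genes, 5 of 32 fell (11 adjusted over the list alone), such as the wall enzyme genes UTR2 (-1.39 ± 0.21) and SCW10 (-1.08 ± 0.15), and the mannoprotein gene CWP1 (1.84 ± 0.23) rose. The mitochondrially encoded median was -0.50, and -0.86 with the negative-control filter. Its call was lost with median centring (-0.33, adjusted p = 0.2, the highest over 16 alternatives) and in the Cy3 channel alone (-0.35). The cell wall median was -0.17, -0.32 without young replicate 2 and -0.37 under scale normalization. It was not called without young replicate 1 (-0.21), with the young arrays averaged as 1 replicate or in the Cy3 channel alone (adjusted p of up to 0.228). Of the 16 alternatives 14 called the mitochondrially encoded and 13 the cell wall list. The mitochondrial ribosomal protein list had a median of -0.28, but 0.23 under scale normalization, where the list was called up (adjusted p = 1.97e-05, against at most 0.0311 over 16 alternatives). Of its 71 genes 1 fell by limma (0 adjusted over the list alone, 21 at an unadjusted p under 0.05) and 3 rose (3 adjusted over the list alone), including MRP8 (1.41 ± 0.14). The gene that fell was MRPL15 (-0.68 ± 0.12), which lay at 0.034 under scale normalization and 0.38 in the Cy3 channel alone. Camera called the last 3 lists (adjusted p between 6.78e-05 and 0.0137; adjusted p between 0.299 and 0.564 with an estimated correlation).

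**Figure D2:**
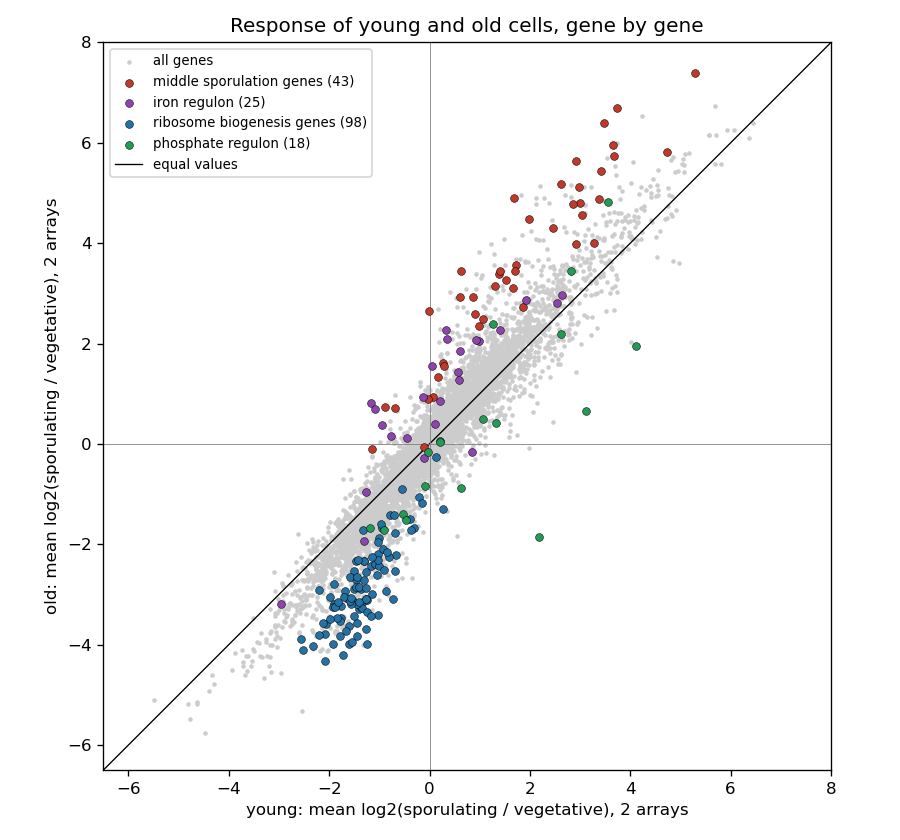
Mean log2 ratio of sporulating over vegetative signal in old cells (vertical axis, 2 arrays) against that in young cells (horizontal axis, 2 arrays), 1 point per gene, with 4 gene lists coloured and a line of equal values. The middle sporulation genes lie mostly above the line, with medians of 3.44 in old and 1.68 in young cells, and the ribosome biogenesis genes below it, with medians of -3.02 and -1.38.

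In all, 419 of 6256 genes differed between old and young cells by limma (275 higher and 144 lower in old), and 1973 had an unadjusted p under 0.05. Every gene named above as past this test had both old arrays on the same side of both young arrays. The naming rule required this of the largest rises and falls, so for them it is no test. The count depended on the normalization, with 1152 genes with median centring in place of loess (425 higher and 727 lower). With background, detrending and normalization changed together it was 0 with processed signals and 0 with the deposited values by limma (1053 and 1199 at an unadjusted p under 0.05). It also rested on the closeness of the old arrays, with 0 genes without old replicate 1 or old replicate 2 (766 and 733 at an unadjusted p under 0.05), 2773 without young replicate 1 and 3682 without young replicate 2.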

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

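The tests of the range of log ratios and of a share of vegetative cells were chosen only after the results were seen. The test of the young and old responses against each other called 419 genes and 23 gene lists. With an estimated correlation camera called 0 lists, with an adjusted p of at least 0.299. Few residual degrees of freedom limit that form, so its lack of calls does not show an effect of correlation. Without old replicate 1 or old replicate 2 limma called 0 genes (766 and 733 at an unadjusted p under 0.05). Of the 419 genes, 18 fell in young and rose in old cells by the fit. Among them, chosen after their values were seen, were the iron uptake genes FET3 (-1.17 in young, 0.82 in old), FTR1 (-1.09, 0.69) and ENB1 (-0.94, 0.37), the polo kinase gene CDC5 (-0.88, 0.74) and the mitotic exit gene SPO12 (-0.68, 0.71). Another 8 genes lay above the vegetative level in young and below it in old cells by the fit. They were PHO84 (2.18, -1.85), the polyphosphate synthesis gene VTC1 (0.62, -0.88), the flavohaemoglobin gene YHB1 (0.79, -0.61), POP1 (0.60, -0.39), JJJ1 (0.59, -0.36), FRM2 (0.46, -0.68), YEF3 and RPL4A. The last 2 were saturated in the vegetative channel on all 4 arrays, so their ratios are upper limits and their direction in young cells is not known. For all genes with opposite signs the vegetative level is the 0 that loess sets. Some values lie close to it, such as UBC1 at -0.25 in young and 0.45 in old cells. Normalization can move signs: the proteasome median in old cells was 1.04 after loess and -0.027 with processed signals. With processed signals and with deposited values limma called 0 genes between the ages.

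The middle sporulation genes differed between the ages by a median of 1.82. Young values were scaled by 1.23, the larger of the slope of old on young and the ratio of their SDs over other genes. A median of 1.30 (95% bootstrap interval 1.19 to 1.46) remained. On these arrays a smaller range of young ratios was thus not the whole cause. All bootstrap intervals resample the genes of a list and do not measure spread between arrays or cultures. A vegetative reference that differed between arrays was not the cause either: the list's median old minus young difference was 0.050 (95% bootstrap interval -0.052 to 0.17) in the vegetative channel and 2.04 in the sporulating channel. One share of young cells that never left the vegetative state would be the same for every list. But the median implied share was 0.795 from 37 middle and 0.496 from 30 early genes, a difference of 0.299 (95% bootstrap interval 0.207 to 0.364). Only genes at least 2-fold up in old cells entered, and such cells were taken to stay at the vegetative level. Cells that left that level without entering meiosis were not covered by this test. Age itself, a different stage of meiosis reached at 6 h, differences between cultures and array position stay open and untested.

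The iron regulon differed by a median of 0.87. After the same scaling of the young values a median of 0.69 (95% bootstrap interval 0.51 to 1.11) remained, so a smaller range on the young arrays was not the whole cause. The vegetative channel differed by -0.059 (95% bootstrap interval -0.14 to 0.068) and the sporulating channel by 0.86, which argues against a change in the reference. Age itself, iron supply in the cultures and array position stay open and untested.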

How the results depend on the processing

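The filter against negative controls and the averaging of the old arrays were chosen after seeing the data. Over 15 alternatives the count of changed genes ran from 3861 to 5194 in young and from 3678 to 5634 in old cells, within 1.5 times the count reported. Of 1153 values of named genes 1140 kept direction and call in young cells, as did 1090 of 1107 in old cells and 519 of 878 in old against young cells, where 322 kept the direction only. Camera called 23 to 26, 21 to 23 and 17 to 23 lists over the settings with the preset correlation, 10 of them the same way between the ages in all 16, and 0, 0 and 0 with an estimated correlation. The count of 419 genes between the ages became 1152 with median centring (375 shared), 75 with scale normalization (67 shared), 235 with a replicate block (227 shared), 58 in the Cy3 channel alone (56 shared) and 3116 with the young arrays averaged. Limma called 0 with processed signals, 0 with deposited values and 0 with the old arrays averaged (1053, 1199 and 729 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 3682: the lone array is then assumed to vary like the other group, so the spread comes from the old pair or from the young pair alone. Of the genes named between the ages, 46 lost the call without either old array, and 9 and 8 gained it without young replicate 1 and 2. Directions turned for OLI1 in old cells (-0.014 with median centring, -0.14 with processed signals). Between the ages they turned with scale normalization for IME1 (-0.74), IME2 (-0.13), DSE2 (0.29), SFC1 (-0.30) and MRPL15 (0.034), and in the Cy3 channel alone for IME1 (-0.30), RPC10 (0.31) and MRPL15 (0.38). Except for the left-out and averaged arrays, the cause was not tested. No filter on dim genes, a filter in both channels and the brightest probe changed nothing and say nothing about stability, and a slide block could not be run, since all arrays share 1 slide. Weak Cy5 signal on young replicate 2 limits ratios of dim genes there.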

Other observations

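The test of vegetative RNA mixed into a young sample was chosen only after its result was seen. Several gene groups were not shifted as lists at either age, although many of their members changed. Glycolysis and fermentation genes rose in 15 and fell in 9 of 29 cases in young cells, and rose in 13 and fell in 9 in old cells. Their list had medians of 0.30 in young and 0.34 in old cells (camera adjusted p = 0.499 and 0.723). With median centring these were -1.03 and -0.88, and camera called the list down (adjusted p = 0.0052 and 0.0314). With processed signals they were -1.27 and -1.01, and camera again called the list down (adjusted p = 0.0117 and 0.0405). With the deposited value table the list lay at -1.28 and -1.04 and was not called. Over 15 alternatives its adjusted p ran from 0.0052 to 0.66 in young and from 0.0314 to 0.982 in old cells. DNA replication genes rose in 11 and fell in 13 of 32 cases in young cells, and rose in 13 and fell in 12 in old cells. Lifespan and rDNA silencing genes rose in 17 and fell in 8 of 35 cases in young cells, and rose in 19 and fell in 10 in old cells. Ergosterol genes rose in 7 and fell in 11 of 24 cases in young cells, and rose in 6 and fell in 15 in old cells. Histone genes rose in 4 and fell in 4 of 11 cases in young cells, and rose in 6 and fell in 3 in old cells. Counts adjusted over each list alone were the same as those over all genes. The adjusted p of these 4 lists ran from 0.102 to 0.969. Of their alternatives, 3 in young and 3 in old cells called the ergosterol list and 2 and 1 the histone list, none the others. The ergosterol medians were -0.33 and -0.52, and -1.26 and -1.45 with the deposited value table, which called the list down. The histone medians were -0.0025 and 0.25, but -1.33 in young cells with the deposited value table and -1.01 in old cells with processed signals, which called the list down in old cells. Median and mean differed in sign for the DNA replication and glycolysis lists at both ages, the histone list in young cells, the mitochondrially encoded and zinc lists in old cells, and between the ages for the DNA replication, respiratory, and COS and YRF1 lists.

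Other nutrient lists were not called by camera at either age (adjusted p between 0.0693 and 0.93, cell wall genes included). Phosphate genes rose in 10 of 18 cases in young and 8 in old cells, zinc genes in 6 of 12 and 5, biotin genes in 5 of 6 and 4, and cell wall genes in 17 of 32 and 16. Falls numbered 4 and 7, 2 and 4, 1 and 1, and 10 and 12 in the same order, and the counts adjusted over each list alone were the same. The cell wall medians were 0.52 and 0.48, but -0.14 and -0.42 with the deposited value table. The zinc medians were 0.41 and -0.14, but -0.21 and -0.69 with processed signals. The phosphate list was called up in young cells when either old array was left out (adjusted p = 0.0463 without old replicate 1 and 0.0463 without old replicate 2, at most 0.208 over 15 alternatives). So was the biotin list, which was also called without young replicate 2 (adjusted p = 0.0266) and in 6 of its alternatives in all (adjusted p at most 0.141). Iron genes rose in 11 and fell in 8 of 25 cases in young cells (adjusted p = 0.772 for the list). Mitotic G2/M and methionine genes had medians of -0.68 and 1.52 in old cells (adjusted p = 0.0842 for each). Between the ages camera called none of the DNA replication, G1/S, G2/M, respiratory, glycolysis, nitrogen starvation, lifespan, retrograde, zinc, biotin, COS and YRF1, and ergosterol lists. Their median differences lay between -0.26 and 0.18, with adjusted p between 0.0886 and 0.892. Over 16 alternatives these medians ran from -0.78 to 0.30, and the adjusted p from 1.69e-06 to 0.96. Both ends of the range of medians came from scale normalization between arrays. It called the nitrogen starvation list down (-0.66 against -0.032, adjusted p = 1.69e-06), as the Cy3 channel alone did (-0.26), and the respiratory list down (-0.28 against 0.0038, adjusted p = 0.00972). It called the G2/M list up (0.30 against 0.16), as the Cy3 channel alone did (0.26). It moved the retrograde median from 0.020 to -0.78 and the biotin median from -0.24 to -0.75 without a call. The zinc list was called without young replicate 2, at a median of -0.30.

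Ribosome biogenesis genes were less reduced on young replicate 1 than on young replicate 2, by a median of 1.26, and so were polymerase I and III genes (0.84) and cytosolic ribosomal protein genes (0.42). The difference was not particular to ribosome production: the biotin (0.59), gluconeogenic (0.52) and zinc (0.50) lists were also higher on young replicate 1, and the seripauperin (-0.35) and respiratory (-0.27) lists lower. Random lists matched on mean intensity differed by -0.015 to 0.18 (middle 95%), and the ribosome biogenesis list lay at percentile 100 of 10000 such lists. Loess had already removed trends with intensity within each array, so matched lists had to differ little. The test therefore cannot decide about an intensity-dependent dye trend on 1 array. Vegetative RNA mixed into young replicate 1 would need a share of 44.4% and would shift early meiotic and gluconeogenic genes by a median of -0.69, but together these differed by 0.11 (95% bootstrap interval -0.11 to 0.37), the early list by -0.050 and the gluconeogenic list by 0.52. A difference between the young cultures in growth or timing, and whether they were separate cultures, stay open and untested.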
